A study of Mus musculus with 12 samples.

How the data were processed

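The data were 12 libraries of messenger RNA from mouse muscle, 6 from vascular anomalies and 6 from normal muscle. Per the labels' protocols, tissue was snap frozen, total RNA was isolated with a Qiagen RNeasy kit, and libraries were made from 1 ug of RNA with an unstranded Illumina TruSeq kit that selects polyadenylated RNA. Per the submitters' processing notes, STAR and limma were used with the mouse build mm10 (GRCm38), with no versions stated. The authors deposited 1 table of 30389 Ensembl genes with log2 values of CPM, read counts scaled to library size. The deposited log2 values had a common floor of -6.707 for genes without reads. After the floor was removed, 100% of the values in every library were whole multiples of 1 step within 0.01. These multiples were taken as reads and gave the library size behind each value. That size held a composition factor of 1.28 to 1.90 in anomaly libraries and 0.636 to 0.715 in normal libraries. The recovered depth ran from 254404 to 18476461 reads in anomaly libraries and from 17380211 to 32155879 in normal libraries. In the library of lowest depth, piece 1 of anomaly animal 1, the recovered units may not be reads as sequenced, as described below. Coordinates and gene types came from a GENCODE annotation of GRCm38, in which 30294 of the 30389 identifiers were found and 95 were not.

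The design, written before the data were examined, assumed a table of counts and gave limma as the test to use if the table held normalised values. Since it held log2 values, limma was used. CPM was recovered from the log2 values, log2(CPM + 1) was averaged over the 2 libraries of each animal, and 14687 genes with a mean of at least 1 CPM in a group were tested between 3 anomaly and 3 normal animals with limma 3.58.1 in R 4.3.3 (trend on, robust off), with Benjamini-Hochberg adjustment at 0.05. A permutation test of 3 animals against 3 cannot give a two-sided p below 0.1 and was not used for genes. Of 36 gene lists fixed beforehand, 33 were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. The epidermis list had too few tested genes, the mitochondrial list was not analysed here, and the sex-linked list served as a check of samples. Lists of cell type markers were read as lists, and no cell was typed. Distances between pieces used the 500 most variable genes and an exact permutation of the pairings. Differences among animals of a group were tested with limma's F test on the libraries, so their p-values measure only the spread between pieces.

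Genes named in the text followed a rule fixed beforehand. It took the 10 higher and 10 lower genes with the largest fold change among those with an adjusted p under 0.05, a mean of at least 3 log2 units and no overlap between anomaly and normal libraries, without predicted genes and immunoglobulin or haemoglobin genes. It added up to 4 members of each list with the smallest p, Cdh5, Pecam1, every member of a list with 5 or fewer measured members, and the 5 genes with the smallest p among anomaly animals. This named 149 different genes. Other genes are named as chosen after their values were seen, as were the further members given for lists whose members moved both ways. A few genes that the rule or the checks for far libraries picked are not reported here.

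Alternatives fixed beforehand were scaling by library totals alone, median-of-ratios factors, trimmed mean of M-values without the 50 most abundant genes, other filters and pseudocounts, each piece alone, all 12 libraries with and without the animal as a random block, stricter thresholds, and leaving out each animal in turn. Added after the data were seen were trimmed mean scaling on all reads, anomaly animal 1 by piece 2 alone, recovered reads summed per animal with voom, the letter of the sample name in place of the piece number, with lesions 1 and 2 of anomaly animal 2 taken as A and B, and the restriction to genes with a mean of at least 50 CPM. The pipeline was tested on simulated data with 200 changed genes. With a coefficient of variation between animals of 0.316, the first value tried, 7% of 2-fold and 88% of 4-fold changes were recovered and 2.06% of calls were false. With 0.2, tried after that result, the values were 45%, 97% and 2.74%. Neither run called a gene or a list when nothing was changed, where limma and camera were applied to 12872 and 12842 genes. The spread in the real animals was not matched to either value. Simulated genes varied independently, whereas estimated correlations within the real lists reached 0.964. The absence of list calls therefore says nothing about lists of correlated genes. Simulated reads were scaled by their known sizes, so scaling when most genes change was not tested.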

Results

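Messenger RNA from mouse muscle was sequenced in 12 libraries from 6 C57BL/6 animals. In 3 animals, called SBxVEC-Cre+ by the submitters, Cre recombinase was placed under the promoter of VE-cadherin, an endothelial adhesion protein, beside the Sleeping Beauty transposase and the onc3 transposon, a DNA element that the transposase moves. Their libraries came from vascular anomalies in muscle. The other 3 animals carried transposase and transposon without Cre and gave normal muscle. Each animal gave 2 libraries, from pieces of tissue or, in anomaly animal 2, from separate lesions, so the animal was the replicate (n = 3 per group). Pieces are numbered here in order of deposit, so piece 1 bears the letter A in anomaly animals 1 and 3 and the letter B in normal animals. In the anomaly group, animal 1 gave 254404 and 14801234 reads, animal 2 gave 11301664 and 9650550, and animal 3 gave 18473628 and 18476461. In the normal group, animal 1 gave 25252967 and 21765755 reads, animal 2 gave 32155879 and 25443460, and animal 3 gave 17380211 and 24791608. A single read weighed 1.85 CPM, a read count scaled to library size, in piece 1 of anomaly animal 1 and at most 0.0719 in the other libraries, so genes near 1 CPM were not resolved in that piece. Its counts may be those of a deeper library divided and rounded up, as described below. The 50 most abundant genes held 14.6% to 22.9% of the reads in anomaly libraries and 47.7% to 50.8% in normal libraries. Ddx3y, a Y-linked gene, averaged 5.82 log2(CPM + 1) in normal animal 2, whose label begins with M, and at most 0.06 in each other animal, so all anomaly animals and 2 of the normal animals lacked Y-linked expression. Transposon insertions were not analysed here.

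The first comparison asked how the transcriptome of anomaly tissue from animals with endothelial transposition differed from that of normal muscle. Anomaly tissue held far more transcripts of endothelium, extracellular matrix, dividing cells and macrophages than normal muscle, and far fewer of the contractile apparatus and of energy metabolism. Of 14687 genes tested with limma, 9318 (63.4%) changed at an adjusted p under 0.05, with 4765 higher and 4553 lower in anomaly tissue. All 3 anomaly animals lay beyond all 3 normal animals in 10725 genes (73.0%), where chance gives 10% for 3 animals against 3. The split of directions depended on the scaling. With library totals alone, 8962 genes were higher and 1850 lower and the median log2 fold change of all genes was 0.97, against 0.09 with the deposited scaling. With trimmed mean scaling recomputed on all reads, 3743 were higher and 6006 lower at a median of -0.33, and computed without the 50 most abundant genes it gave 3953 higher and 6106 lower at a median of -0.29. Fold changes of single genes below are anomaly minus normal in log2(CPM + 1) with the standard error of the fit (n = 3 animals per group).

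Among the genes that separated all 12 libraries by group, the largest rises included matrix and mitotic genes. Tnc, encoding tenascin C (ENSMUSG00000028364, protein coding, GRCm38 chromosome 4, 63959785 to 64047015), rose by 6.85 ± 0.92 (adjusted p = 0.00136). Postn, encoding periostin (ENSMUSG00000027750, protein coding, chromosome 3, 54361109 to 54391037), rose by 6.73 ± 0.31 (adjusted p = 1.05e-04). Col18a1, encoding a basement membrane collagen (ENSMUSG00000001435, protein coding, chromosome 10, 77052178 to 77166548), rose from 9.92 ± 2.22 to 1122 ± 249 CPM (SD, n = 3). Mki67 (ENSMUSG00000031004, protein coding, chromosome 7, 135689784 to 135716361) rose by 6.51 ± 0.18, from 0.488 ± 0.186 to 144.6 ± 2.88 CPM (SD, n = 3). Its pieces stood at 5.96 and 7.88 log2(CPM + 1) in anomaly animal 1, 7.52 and 6.72 in animal 2, and 7.02 and 7.29 in animal 3. Mest, Marcksl1, Top2a, Igfbp3, Clca2 and Cd109 followed with rises from 5.74 to 6.45. The largest falls were all in skeletal muscle genes. Myh4, encoding the myosin of fast glycolytic fibres (ENSMUSG00000057003, protein coding, chromosome 11, 67238029 to 67260446), fell by 9.53 on the log2 scale (standard error 0.93, adjusted p = 4.81e-04), from 112807 ± 24476 to 226 ± 186 CPM (SD, n = 3). Ckm, encoding muscle creatine kinase (ENSMUSG00000030399, protein coding, chromosome 7, 19404776 to 19422841), had a log2 fold change of -7.92 ± 1.45 (adjusted p = 0.00404). Myom2, Actn3, Mybpc2, Pvalb, Ampd1, Pygm, Atp2a1 and Mybph had values from -8.33 to -7.70, of which Atp2a1 was not called without anomaly animal 1 or 2 (adjusted p = 0.0778 and 0.0704).

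**Figure D1:**
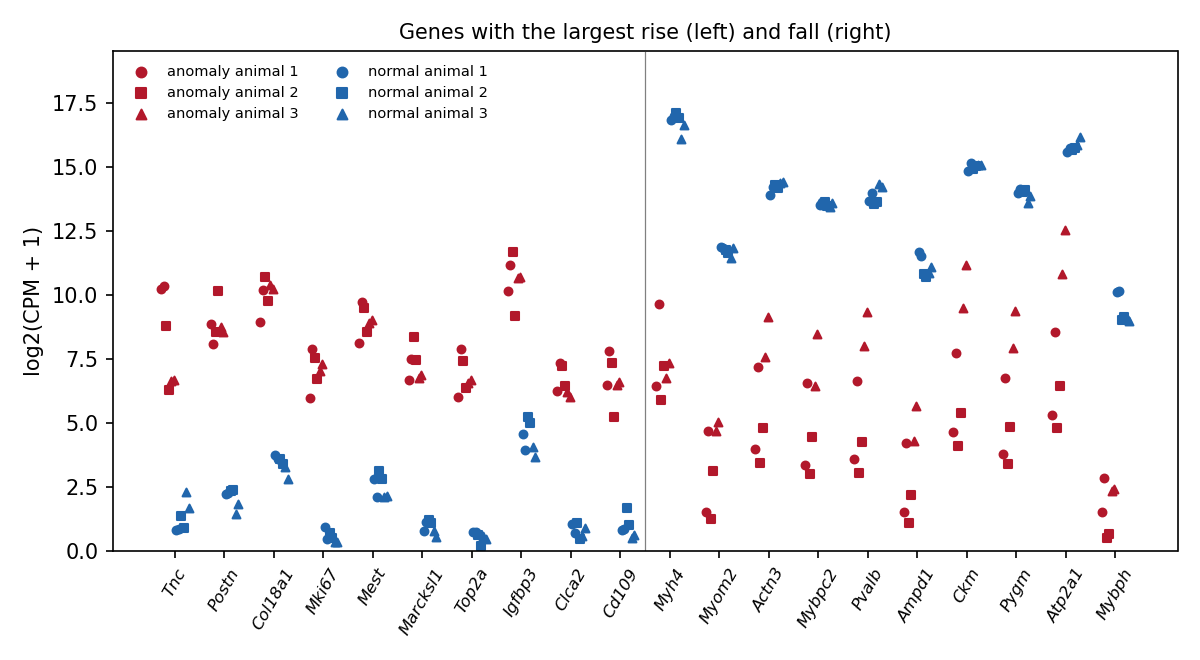
Expression in log2(CPM + 1) of the 10 genes with the largest rise and the 10 with the largest fall, with 1 point per library, anomaly in red and normal muscle in blue, and marker shape giving the animal. Genes were chosen so that all 6 anomaly libraries lie beyond all 6 normal libraries. Among anomaly animals, the mean over pieces of the lower genes is highest in animal 3 for all but Myh4.

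Endothelial genes were examined first among the gene lists, since Cre was driven by an endothelial promoter. Cdh5, which encodes VE-cadherin itself (ENSMUSG00000031871, protein coding, chromosome 8, 104101625 to 104144511), rose by 3.5 ± 0.27 (adjusted p = 2.58e-04), from 97.3 ± 20.2 to 1141 ± 138 CPM (SD, n = 3), and Pecam1 (ENSMUSG00000020717, protein coding, chromosome 11, 106654217 to 106750628) rose by 3.80 ± 0.26 (adjusted p = 1.99e-04). Of 28 endothelial genes, 25 were higher, 0 lower and 3 not called, and 25 were higher adjusted over the list alone, with a median log2 fold change of 3.16. The median was 2.47, 3.66 and 3.73 in anomaly animals 1, 2 and 3. Plvap, of fenestrated endothelium, rose by 4.58 ± 0.30 and Emcn by 4.03 ± 0.17. Among 16 arterial and Notch genes, 11 were higher, 0 lower and 5 not called, and 12 were higher adjusted over the list alone, at a median of 2.61. Notch4 rose by 3.90 ± 0.19, Dll4 by 3.85 ± 0.25 and Efnb2 by 3.56 ± 0.31. Camera, limma's test of a list against all other genes, called both lists higher (adjusted p = 5.46e-09 and 1.69e-04). Neither call held, at adjusted p = 0.595 with an estimated correlation.

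Angiogenesis genes moved both ways. Of 20 angiogenesis and tip cell genes, 12 were higher, 5 lower and 3 not called, with 13 higher and 5 lower adjusted over the list alone. Mcam rose by 4.37 ± 0.22, Plxnd1 by 3.69 ± 0.28 and Pdgfb by 2.59 ± 0.18. Vegfa, Vegfb and Angpt1, chosen after their values were seen, were lower by log2 fold changes of -2.46 ± 0.73, -3.21 ± 0.30 and -2.41 ± 0.32. Muscle fibre transcripts fell in the same tissue, so the falls of these genes need not lie in vascular cells. Camera called the list higher (adjusted p = 0.0391, and adjusted p = 0.595 with an estimated correlation), but not without anomaly animal 1 (adjusted p = 0.0532), by its piece 2 alone (0.0544), by piece 1 of every animal alone (0.0554), by pieces lettered A alone (0.0607) or with library totals alone (0.362). The call also ended in voom fits with the animal as a random block (adjusted p = 0.0852), with the piece number or the piece letter as a further block (0.0866 and 0.0722) and on reads summed per animal (0.0625). Of 18 mural and smooth muscle genes, 12 were higher, 2 lower and 4 not called, the same counts as adjusted over the list alone, with Pdgfrb at 3.72 ± 0.46 and Cspg4 at 2.54 ± 0.30. The lower members were Abcc9 (-2.04 ± 0.29) and Tpm2 (-4.77 ± 1.2), both also made by muscle fibres. The mural list was called higher (adjusted p = 0.0190, and adjusted p = 0.595 with an estimated correlation), but not without anomaly animal 3 (adjusted p = 0.0617) or with library totals alone (adjusted p = 0.157). Of 10 venous genes, 5 were higher, 0 lower and 5 not called, with 5 higher adjusted over the list alone, and Nrp2 rose by 3.80 ± 0.25, while the list was not called (adjusted p = 0.105), although it was without a filter (0.0469) and at a mean of at least 5 CPM (0.0349). Of 9 lymphatic genes, 4 were higher, 2 lower and 3 not called, the same counts as adjusted over the list alone. Flt4 rose by 4.07 ± 0.20 and Ccl21a had a log2 fold change of -1.51 ± 0.22, and the list was not called (adjusted p = 0.339).

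Lists of genes linked to human vascular anomalies and flow response had members that moved both ways. Of 20 genes of PI3K, RAS and G protein signalling, 10 were higher, 4 lower and 6 not called, with 10 higher and 5 lower adjusted over the list alone. Tek rose by 2.43 ± 0.31 and Akt1 by 1.96 ± 0.27, and Pik3ca, chosen after its value was seen, was lower at -0.71 ± 0.20. That list was not called (adjusted p = 0.219). Of 20 measured genes of hereditary telangiectasia, cavernous malformation and flow response, 12 were higher, 2 lower and 6 not called, the same counts as adjusted over the list alone. Nos3 rose by 3.94 ± 0.16, Acvrl1 by 3.54 ± 0.40 and Adamts4 by 4.92 ± 0.85. Camera called this list higher (adjusted p = 0.0298, and adjusted p = 0.595 with an estimated correlation), but not without anomaly animal 2 (adjusted p = 0.0501) or animal 3 (adjusted p = 0.0643).

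Matrix genes formed one of the broadest rises. Of 33 collagen and matrix genes, 29 were higher, 0 lower and 4 not called, and 29 were higher adjusted over the list alone, with a median log2 fold change of 4.26 (camera adjusted p = 2.47e-07, and adjusted p = 0.595 with an estimated correlation). Bgn rose by 4.26 ± 0.23 and Col8a1 by 4.11 ± 0.26. The fibroblast list was not called. Of 15 fibroblast markers, 5 were higher, 1 lower and 9 not called, with 5 higher and 0 lower adjusted over the list alone. The higher ones included Thy1 (3.91 ± 0.35), Col1a1 (4.88 ± 0.83) and Col3a1 (3.93 ± 0.74), and the lower one was Clec3b (-2.25 ± 0.75). The median of the fibroblast list was -0.15 while its mean was 0.74 and its test direction was up (adjusted p = 0.450). Of 18 coagulation and fibrinolysis genes tested, 11 were higher, 0 lower and 7 not called, with 10 higher adjusted over the list alone. S100a10 rose by 3.15 ± 0.16, Tfpi by 3.63 ± 0.41 and Plat by 3.46 ± 0.49 (list adjusted p = 0.00202, adjusted p = 0.595 with an estimated correlation, and adjusted p = 0.0600 with library totals alone).

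Macrophage, interferon, inflammatory cytokine and platelet lists were called higher in anomaly tissue. Of 19 macrophage genes, 18 were higher, 0 lower and 1 not called, with 18 higher adjusted over the list alone and animal medians of 4.28, 4.57 and 2.33 (camera adjusted p = 1.44e-04). Mpeg1 rose by 5.70 ± 0.78 and Ctss by 4.95 ± 0.65. All 19 interferon-stimulated genes were higher, 19 also adjusted over the list alone, led by Rsad2 at 4.97 ± 0.44 and Bst2 at 3.77 ± 0.37 (camera adjusted p = 3.31e-06). Of 19 inflammatory cytokine genes, 10 were higher, 0 lower and 9 not called, with 7 higher adjusted over the list alone. Tgfb1 rose by 4.43 ± 0.21 and Ccl2 by 3.85 ± 0.83 (camera adjusted p = 0.00673, and 0.288 with library totals alone). Of 12 platelet genes tested, 10 were higher, 1 lower and 1 not called, with 11 higher and 1 lower adjusted over the list alone. Clec1b rose by 3.38 ± 0.23 and Itgb3 by 4.62 ± 0.85 (camera adjusted p = 0.0138, 0.270 with library totals alone and 0.0794 at a mean of at least 5 CPM). All 4 of these list calls were lost, at adjusted p = 0.595 with an estimated correlation.

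Other blood lists were not called in the planned fit. Of 11 erythroid genes tested, 7 were higher, 0 lower and 4 not called, with 7 higher adjusted over the list alone (adjusted p = 0.0722). Their median was 5.75, 3.13 and 1.13 in anomaly animals 1, 2 and 3, and without animal 3 the list was called (adjusted p = 0.00917). It was also called with trimmed mean scaling on all reads (0.0145) or without the 50 most abundant genes (0.0152), without a filter (0.0262), by piece 2 alone (0.0375) and by letter B alone (0.0426). Alas2 rose by 4.35 ± 1.28, and Hba-a2 and Hbb-bt by 4.99 ± 1.41 and 4.76 ± 1.46, although haemoglobin genes share reads with near-identical copies and their separate values are uncertain. Of 10 neutrophil genes tested, 1 was higher, 0 lower and 9 not called, with 0 higher by limma adjusted over the list alone, where 1 had an unadjusted p under 0.05 (adjusted p = 0.183 for the list, and 0.0473 without anomaly animal 3), and Csf3r rose by 3.01 ± 1.0. Without anomaly animal 1, Alas2 stood at 2.82, Hbb-bt at 3.07 and Csf3r at 1.87. Calls of these 3 and Hba-a2 ended without normal animal 1 or 3 (adjusted p from 0.0655 to 0.105), those of all but Hba-a2 without normal animal 2 (0.0536 to 0.0911), and those of Hbb-bt and Csf3r without anomaly animal 2 (0.0638 and 0.0727). Of 18 lymphocyte genes tested, 8 were higher, 1 lower and 9 not called, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.183). Ighm, the constant region of immunoglobulin M, had a log2 fold change of -3.47 ± 0.44, against 2.41 ± 0.45 for Lck. Of 7 mast cell genes tested, 2 were higher, 0 lower and 5 not called, with 1 higher adjusted over the list alone (adjusted p = 0.305), and Kit rose by 5.02 ± 0.21 while Cma1 stood at 0.36 ± 0.61. Of 9 blood progenitor genes tested, 5 were higher, 3 lower and 1 not called, the same counts as adjusted over the list alone, with Runx1 at 3.22 ± 0.33 and Tfrc at -3.16 ± 0.30 (adjusted p = 0.219).

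Contractile and fast fibre genes had the lowest medians of the lists examined. Of 30 contractile genes, 0 were higher, 27 lower and 3 not called, with 28 lower adjusted over the list alone, and the median log2 fold change was -6.96 (camera adjusted p = 1.44e-06). The loss differed among animals, with medians of -8.39, -9.32 and -3.31 in anomaly animals 1, 2 and 3, and between pieces, at -9.82 and -6.96 in animal 1, whose first piece was the shallow one, -10.09 and -8.76 in animal 2, and -4.07 and -2.55 in animal 3. Of 12 fast fibre genes, 0 were higher, 11 lower and 1 not called, with 11 lower adjusted over the list alone, at a median of -7.36 (camera adjusted p = 4.24e-04). Mybpc2 had a value of -8.16 ± 0.92 and Pvalb one of -8.07 ± 1.24. All 42 nuclear genes of oxidative phosphorylation were lower, 42 also adjusted over the list alone, at a median of -2.73 (camera adjusted p = 2.45e-11), among them Sdhb at -3.07 ± 0.37 and Cox5a at -2.96 ± 0.34. Of 20 fatty acid oxidation genes, 0 were higher, 19 lower and 1 not called, the same counts as adjusted over the list alone, with Decr1 at -2.75 ± 0.27 (camera adjusted p = 1.63e-06). Of 20 glycolysis genes, 3 were higher, 17 lower and 0 not called, the same counts as adjusted over the list alone (camera adjusted p = 5.01e-04). Phka1 had a value of -6.24 ± 0.60, while the 3 higher members were the non-muscle forms Hk1 (3.56 ± 0.36), Eno1 (1.73 ± 0.60) and Pgam1 (1.72 ± 0.62). These 5 calls were lost, at adjusted p = 0.595 with an estimated correlation.

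**Figure D2:**
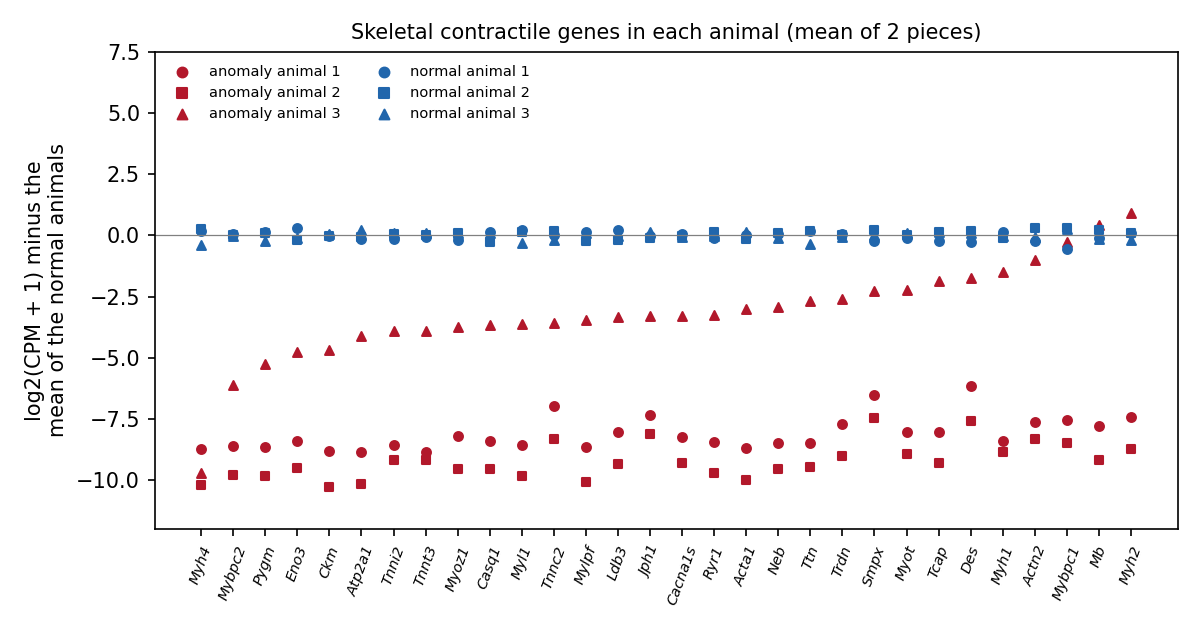
Log2(CPM + 1) of 30 skeletal contractile genes in each animal (mean of 2 pieces) minus the mean of the normal animals, with genes ordered by anomaly animal 3. Anomaly animals 1 and 2 lie at similar depths across genes, whereas animal 3 ranges from a loss of Myh4 as deep as theirs to values above normal muscle for Myh2 and Mb.

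Slow fibre and regeneration genes moved less evenly. Of 10 slow fibre genes, 1 was higher, 2 lower and 7 not called, with 0 by limma adjusted over the list alone, where all 10 were tested and 3 had an unadjusted p under 0.05 (adjusted p = 0.466 for the list). Tpm3 rose by 2.39 ± 0.68 and Myl3 had a value of -4.04 ± 1.45, and the animal medians were -2.20, -2.38 and 1.51. Tpm3 was not called without anomaly animal 2 or normal animal 1 or 3 (adjusted p = 0.0538, 0.0549 and 0.0729), nor Myl3 without anomaly animal 1 or 2 or normal animal 1 or 2 (0.111 to 0.144). Of 15 muscle regeneration genes tested, 1 was higher, 7 lower and 7 not called, with 1 higher and 5 lower adjusted over the list alone (adjusted p = 0.219, 0.0226 without anomaly animal 3 and 0.00854 with library totals alone). Myod1 had a value of -4.06 ± 0.76 and Vcam1, also an endothelial gene, rose by 3.0 ± 0.51. Of 12 atrophy and denervation genes, 3 were higher, 4 lower and 5 not called, the same counts as adjusted over the list alone, with Mstn at -5.57 ± 0.33 and Trim63 at -5.88 ± 1.07 (adjusted p = 0.466). Of 13 adipocyte genes, 1 was higher, 3 lower and 9 not called, with 0 higher and 1 lower adjusted over the list alone, Car3 at -5.71 ± 0.94 and Pparg at 2.42 ± 0.64, not called without normal animal 3 at an adjusted p = 0.0554 (list adjusted p = 0.220, 0.0266 without anomaly animal 2, 0.00693 with library totals alone, 0.0378 by piece 1 alone and 0.0243 by letter A alone). The lower adipocyte members were Car3, Plin4 and Pnpla2, at 4163, 342 and 288 CPM in normal muscle. Their fall could not be assigned to fat cells or to muscle fibres. Of 10 peripheral nerve genes tested, 0 were higher, 4 lower and 6 not called, with 3 lower adjusted over the list alone and Mbp at -1.59 ± 0.34 (adjusted p = 0.400 for the list). Piece 2 of normal animal 1 and piece 1 of normal animal 3 stood apart, with nerve list medians of 1.85 and 0.89 against -0.88 to -0.31 in the other normal libraries and Mbp at 7.15 and 6.41 against 2.93 to 4.16. Mbp was not called by piece 1 or piece 2 alone (adjusted p = 0.131 and 0.218). Only 2 epidermal genes were tested, Krt10 (-0.57 ± 0.20, adjusted p = 0.0440, 0.0754 to 0.127 without any 1 animal but anomaly animal 3, and a value of 0.19 with library totals alone) and Krt5 (0.71 ± 0.58, adjusted p = 0.313), so the list had no test, and 0 of the 2 were called by limma adjusted over the list alone, where 1 had an unadjusted p under 0.05.

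Proliferation genes rose in all 3 anomaly animals, with the pieces of animals 1 and 2 lying apart. Of 25, 24 were higher, 0 lower and 1 not called, with 24 higher adjusted over the list alone, at a median log2 fold change of 4.11 and animal medians of 4.38, 4.31 and 3.94 (camera adjusted p = 4.57e-12, and adjusted p = 0.595 with an estimated correlation). Cdk1 rose from 0.183 ± 0.0195 to 63.8 ± 4.90 CPM and Foxm1 from 0.325 ± 0.0982 to 44.4 ± 3.97 CPM (SD, n = 3). In normal muscle these genes lay near the floor, with a median of 5 to 12 reads per gene and library. Of 16 hypoxia genes, 2 were higher, 7 lower and 7 not called, the same counts as adjusted over the list alone (adjusted p = 0.466). Hmox1 rose by 5.28 ± 1.11 and Ldha had a value of -3.62 ± 0.60, and the list median was 1.44 in anomaly animal 1 against -0.74 and -1.22 in animals 2 and 3. Of 13 immediate early and heat shock genes, 5 were higher, 1 lower and 7 not called, the same counts as adjusted over the list alone, with Ier2 at 2.87 ± 0.35 and Nr4a1 at -3.66 ± 0.27 (adjusted p = 0.253). The 13 mitochondrially encoded genes fixed as a list were not analysed here. Of 5 sex-linked genes tested, 0 were called by limma and 0 had an unadjusted p under 0.05, with Xist at 3.38 ± 1.72 (adjusted p = 0.126), and Ddx3y at -1.90 ± 1.55 (adjusted p = 0.310). Both rested on normal animal 2, without which Xist stood at 1.24 (adjusted p = 0.0368) and Ddx3y was not tested, while Ddx3y stood at -2.87 without normal animal 1 or 3.

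**Figure D3:**
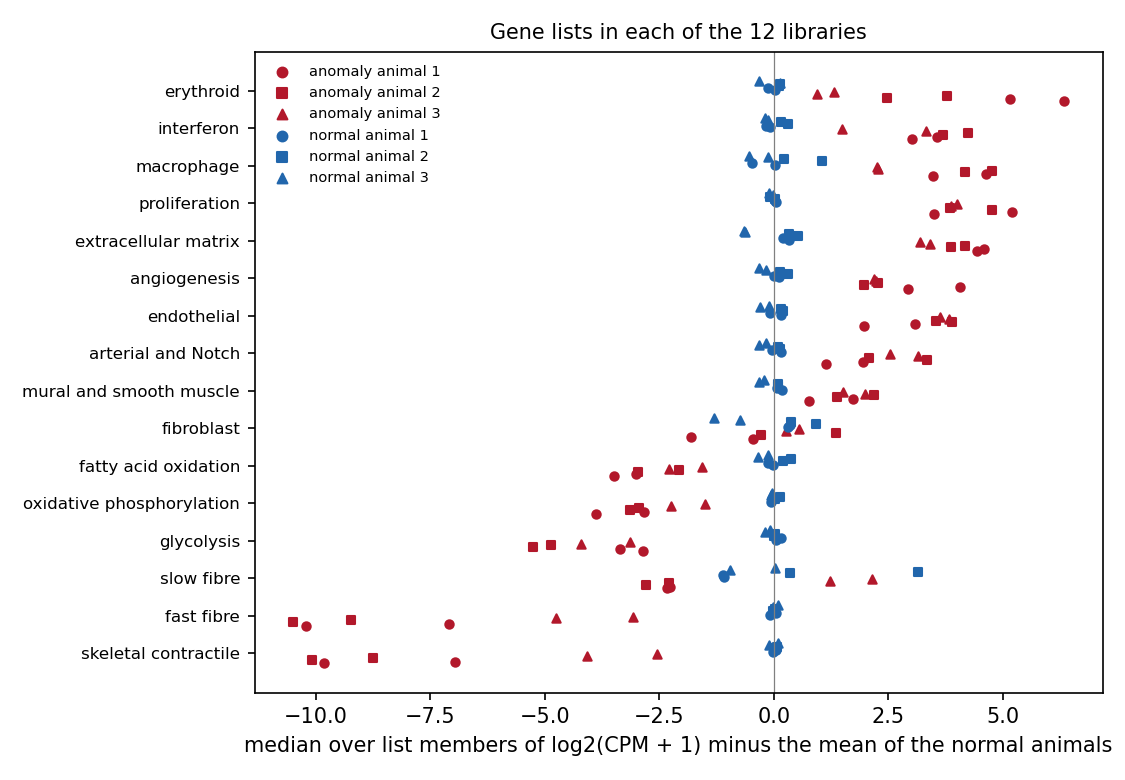
Median over the members of 16 gene lists of log2(CPM + 1) minus the mean of the normal animals, with 1 point per library, anomaly in red and normal muscle in blue, and marker shape giving the animal. Contractile and fast fibre medians lie lowest in anomaly animals 1 and 2, and erythroid medians highest in animal 1.

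The next comparison asked whether pieces of tissue from an animal resembled each other more than pieces of different animals in the same group. Pieces of an animal were on average closer to each other than to pieces of other animals of their group. Over the 500 genes most variable across all 12 libraries, the distance (root mean square difference in log2 units) averaged 1.22 ± 0.12 between pieces of an anomaly animal (SD, n = 3 pairs) and 2.97 ± 0.97 between pieces of different anomaly animals (SD, n = 12 pairs). In normal muscle the averages were 0.42 ± 0.03 within and 0.69 ± 0.09 between animals, but the anomaly group was not tested against the normal group on genes chosen this way, and between the groups the average was 5.38 ± 1.19 (SD, n = 36 pairs). The ratio of distances within animals to those between them was 0.445 (exact one-sided permutation p = 0.00444, the smallest that the 225 pairings allow), and 0.777 without anomaly animal 3 (exact permutation p = 0.0222, the smallest then possible). The separate lesions of anomaly animal 2 had 122 genes that differed by at least 3 log2 units, against 1 gene between the pieces of anomaly animal 3, 32 in anomaly animal 1 with its shallow piece, and 6 to 12 in the normal animals. That cutoff was chosen after the values were seen, and below it the pieces of anomaly animal 3 also differed. Their contractile medians were -4.07 and -2.55. A chi-square of read counts per degree of freedom, which grows with depth, was 109.8 between them and 94.1 between the lesions of animal 2. In the lesions of anomaly animal 2, the adipocyte list had a median of -1.44 (lesion 1) and 2.51 (lesion 2) against normal muscle. The lesions therefore differed in fat markers.

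The last comparison asked which genes differed among the 3 anomaly animals, with the same test in normal muscle as background. Elastin, an imprinted growth factor locus, a slow myosin and a receptor of activated lymphocytes led the anomaly group. Of 13815 genes, 2252 (16.3%) differed among anomaly animals by limma's F test, and 2058 of 12601 (16.3%) differed among normal animals, against the spread between pieces only. The 5 genes with the smallest p in the anomaly group had an adjusted p = 1.52e-04. Eln (ENSMUSG00000029675, protein coding, chromosome 5, 134702593 to 134747323) stood at 1.55, 6.12 and 7.43 log2(CPM + 1) in animals 1, 2 and 3, against 4.17 to 5.45 in normal animals. Tnfrsf9 (ENSMUSG00000028965, protein coding, chromosome 4, 150914562 to 150946102) stood at 7.81, 3.75 and 1.22. Acoxl (ENSMUSG00000027380, protein coding, chromosome 2, 127838876 to 128123873) stood at 1.11, 0.61 and 6.91, and Myh7, encoding slow myosin (ENSMUSG00000053093, protein coding, chromosome 14, 54970684 to 54994626), at 1.4, 0.25 and 7.23. Igf2os (ENSMUSG00000086266, antisense, chromosome 7, 142659693 to 142670356) stood at 0.29, 7.01 and 6.12, but the kit did not mark strand, so its reads cannot be separated from those of Igf2. In the shallow piece 1 of animal 1, Eln, Acoxl and Myh7 each stood at 1.51, the value of a single read there, and Igf2os at 0. Piece 2 of that animal stood at 1.60, 0.70, 1.29 and 0.58 for these genes. Their means in animal 1 and their p-values rest partly on a piece that did not resolve them. Of 30 contractile genes 28 differed among anomaly animals and 3 among normal animals, and erythroid genes gave 10 of 11 against 1 of 7. Other lists had fewer calls among anomaly than among normal animals. Matrix genes gave 11 of 33 against 24 of 32, and fibroblast genes 6 of 15 against 13 of 15. Fatty acid oxidation genes gave 4 of 19 against 12 of 20. Proliferation genes gave 0 of 25 by limma's F test (1 at an unadjusted p under 0.05) against 2 of 8. These counts do not show in which group the animals of a list differed more, and that was not tested. Each group was tested against its own pieces, and partly on different genes. The distance between pieces of an animal, over the most variable genes, averaged 1.22 in the anomaly group and 0.42 in normal muscle. Without the filter 0 genes were called by limma among anomaly animals, where 4407 had an unadjusted p under 0.05, and 1631 among normal animals. The counts also rested on single animals. In the anomaly group 389, 3472 and 997 genes were called without animal 1, 2 or 3, and in the normal group 1311, 672 and 1198.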

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

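The tests of the shallow library, of muscle genes and of proliferation genes were chosen after the results were seen, and only the counts over regroupings of the animals were planned. A library far from the other 5 of its group was looked for in 306 values, of which 13 stood out, 12 of them given here, and chance does so in about 1 in 20 groups. In piece 1 of anomaly animal 1 a read weighed 1.85 CPM, against at most 0.0581 in the other anomaly libraries. The same piece stood apart for Tek, at 5.91 log2(CPM + 1), for Hdc, at 6.33, and for the Y-linked Eif2s3y, at 1.51, which is the value of a single read there. Lesion 2 of anomaly animal 2 stood apart for Postn, at 10.16, and Col3a1, at 11.74. In normal muscle, piece 2 of animal 2 stood apart for the slow fibre genes Tpm3, at 8.10, Myh7b, at 4.80, and Myl2, at 8.32. Piece 1 of normal animal 1 was highest for Krt5, at 0.073, where all others were at 0, for Ccl2, at 0.78, and for Fosb, at 1.49.

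Piece 1 of anomaly animal 1 held 254404 reads but 18740 detected genes. Random sampling of as many reads from piece 2 of that animal would give 12304 detected genes, so the observed number was 1.52 times too high, while this ratio was 1.03 to 1.10 in the other 11 libraries. In the piece, 40.4% of the detected genes had exactly 1 read, against 14.9% from sampling. Piece 2 thinned to the same number of genes, divided by a constant and rounded up gave 39.7%, so a deeper library whose counts were divided and rounded up is a candidate explanation for these values, and its low genes would then be overstated. The number of genes changed was 9316 with piece 2 standing for that animal, of which 8881 were called before.

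Contractile genes stood at 0.432% and 0.139% of normal muscle in anomaly animals 1 and 2 and at 11.6% in animal 3, but pieces of an animal differed, at 0.0950% in the shallow piece and 0.778% in piece 2 of animal 1, 0.0630% and 0.192% in animal 2, and 5.84% and 17.2% in animal 3. Across 27 abundant contractile genes the SD of the log2 ratio was 0.41 in animal 1 (0.34 by piece 2 alone) and 0.59 in animal 2, within 3 times the largest SD among normal animals (0.28), a bound set after these values were seen, so a smaller share of muscle fibres of unchanged makeup may account for the fall there. In animal 3 that SD was 2.10, with Myh4 at -9.72 and Myh2 at 1.07. A smaller share of fibres with the makeup of the sampled normal muscle does not give this. Whether the tissue of animal 3 came from a muscle of another fibre makeup was not tested, so changed fibres cannot be told apart from another muscle. With library totals alone the contractile median was -7.19 and -8.29 in anomaly animals 1 and 2. The median fold change of the list, animal 3 included, was -5.88, far below the -1 set for scaling as a cause. Composition factors ran only from 0.636 to 1.90, so that bound could not have been reached. The values show only that the fall remains with either the deposited scaling or library totals. Reads strayed from normal libraries stay open as the source of the last muscle reads in animals 1 and 2. In animal 2, 2.32 Y-linked reads would be needed and 2 were found, too few to decide. The number needed was not computed for animal 1. Its piece 2 had the Y-linked genes Kdm5d and Uty at 0.063 and Eif2s3y and Ddx3y at 0.124 log2(CPM + 1). Normal animals 1 and 3, which lacked Y-linked expression, also had values up to 0.10 for such genes.

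On log2(CPM + 1), the measure tried first, the median rise of proliferation genes minus that of endothelial genes was 1.91, 0.65 and 0.21 in anomaly animals 1, 2 and 3, while the normal animals ran from -0.17 to 0.19, a range wider than the lowest value of 0.21, so more endothelial cells with unchanged proliferation could not be told apart from a rise of its own. With library totals alone the lowest was -0.13, and with a pseudocount of 5 it was -0.94, but a larger pseudocount shrinks a rise from a low level by construction, and scaling, common to both lists, acts here through the pseudocount, so these 2 tests say nothing about the cause. Going from a pseudocount of 1 to 0.1 raised the difference by at least 1.43 in every anomaly animal. This follows largely from the same construction, and shows only that the pseudocount of 1 did not enlarge the difference. A second measure, CPM ratios without a pseudocount, was chosen after the first had left the question open, and gave 3.59, 2.40 and 2.08, the smallest being 2.08 against at most 0.18 in normal animals. Because the measures differ and the genes had 5 to 12 reads in normal libraries, the question stays open, and the shallow piece alone is not the cause, since piece 2 of anomaly animal 1 gave 3.71.

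With 3 animals against 3 there are 10 splits, so no share under 0.05 is possible. For genes, 1 split, the real one, gave as many calls, with 9318 against a highest other of 0. Each other split had animals of both groups on each side, so the group difference entered the spread and held calls down. That 0 therefore does not measure what chance would give. For lists, 9 splits gave at least as many, with 17 in the real split and 21 in the highest other, each of which still kept 2 animals of 1 group together on each side.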

How the results depend on the processing

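Called genes between groups numbered 7256 to 10158 when each animal was left out in turn (3593 to 5297 higher, 3591 to 4861 lower), and the other alternatives gave 6427 (adjusted p under 0.01) to 11022 (12 libraries as independent), all within 1.5 times 9318. Library totals alone moved the split to 8962 higher and 1850 lower, sharing 6615 genes with the 9318, by shifting the median of all genes. Of 33 lists tested, camera called 17 at the preset correlation and 0 with an estimated correlation (1, proliferation, at an unadjusted p under 0.05), and fry called 23, namely those 17 and the venous, lymphatic, PI3K and RAS, mast cell, blood progenitor and early response lists. The voom fit with the animal as a random block called 10035 genes and 16 lists, and with the piece number as a further block 10022 genes and 16 lists. Piece numbers follow the order of deposit and join letters A of anomaly animals 1 and 3 with letters B of normal animals, so the letter was used as the block instead, which called 10023 genes and 16 lists. All 3 fits lost the angiogenesis list. Letters A alone called 8403 genes and 17 lists, and letters B alone 8050 and 18. Animals sharing a number across groups are different animals by their labels, so the numbers do not pair them. Their deviations correlated weakly, at 0.05, 0.08 and 0.04, although each was highest with its own number. Among anomaly animals 0 genes were called by limma without a filter (4407 at an unadjusted p under 0.05), 741 among genes of at least 50 CPM, which are fewer, and 389 to 3472 with an animal left out. Among normal animals 687 were called at 50 CPM and 672 to 1311 with an animal left out. The piece distance ratio was 0.319 to 0.597 under other measures, and 0.370 to 0.777 with an animal left out (exact permutation p = 0.0222, the smallest then possible). Median signs reversed only in lists and genes that were not called, and in Krt10, and the cause was not tested. With library totals alone the fibroblast list stood at 0.93, atrophy at 0.44, nerve at 0.68, hypoxia at 0.92 and Krt10 at 0.19. The nerve list stood at 0.10 with median-of-ratios factors, 0.13 without a filter, 0.26 at a mean of at least 5 CPM, 0.14 at 1 CPM in 3 animals, and 0.34 by piece 1 alone. The lymphocyte list stood at -0.35 at a mean of at least 5 CPM, and the fibroblast list at 0.16 by piece 2 alone. Eln stood at -0.25 with trimmed mean scaling without the 50 most abundant genes and -0.19 on all reads. The mast cell list and Cma1 both stood at -0.46 in voom with the animal as a block, at -0.59 and -0.60 with the piece number block, both at -0.51 with the letter block, and both at -0.012 with reads summed per animal. With an animal left out, fibroblast ran from -0.75 to 0.41, mast cell from -0.51 to 0.78, hypoxia from -0.89 to 0.43, nerve from -0.59 to 0.016, Cma1 from -0.32 to 0.78 and Eln from -0.98 to 1.96. Of 4512 values of named genes and lists under the alternatives, 4245 kept direction and side of the threshold, 192 were no longer past it, 42 newly passed it and 33 reversed. DESeq2 on animal sums was not run, and recovered reads summed per animal were fitted with voom. Depth limits low genes most in piece 1 of anomaly animal 1.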

Other observations

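The genes, cutoffs and counts below were chosen after the values were seen. Several imprinted genes were higher in anomaly animals 2 and 3 than in animal 1. Igf2 stood at 13.67 and 13.68 log2(CPM + 1) in anomaly animals 2 and 3, against 4.84 in animal 1 and 5.36 to 5.73 in normal muscle, and H19, its neighbour, at 12.89 and 12.86, against 4.44 in animal 1 and 7.91 to 10.04 in normal muscle. The values of animal 1 average its shallow piece, with Igf2 at 3.60 and H19 at 3.07, and its piece 2, at 6.07 and 5.80. By piece 2 alone, Igf2 lay above the normal animals and not below them. Of 13 imprinted genes picked by hand, 8 differed among anomaly animals by limma's F test, against 16.3% of all genes tested, and 7 of these were higher in both animals 2 and 3 than in animal 1. The class was not tested for enrichment. Plagl1 stood at 2.18, 7.26 and 7.85, Dlk1 at 1.63, 5.69 and 5.49, and Peg3 at 1.97, 8.50 and 8.62 in animals 1, 2 and 3. The other 6 were not both called and higher in animals 2 and 3 than in animal 1. Grb10 (7.18, 7.65 and 7.72), Ndn (2.31, 2.68 and 3.10) and Mest had that order without being called. Peg10 was highest in animal 2 alone, at 2.04, 4.58 and 1.64, and Grb10, Meg3, Ndn, Nnat and Mest were not called, Mest standing at 8.92, 9.01 and 8.96, with 2.12 to 2.95 in normal muscle. Between groups, 5 of the 13 were higher and 0 lower. The labels give no ages, and no explanation was tested.

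Single animals also carried genes of their own. A gene lay at least 8-fold beyond every library of all other animals in 21 cases for anomaly animal 1, 1 for animal 2 and 7 for animal 3, and in 0, 6 and 0 cases for the normal animals, where 4 of the 6 were Y-linked. Anomaly animal 1 was marked by haemoglobin genes, Alas2 at 10.46, Thbs1 at 10.73 and the tip cell gene Esm1 at 6.76. Animal 2 was marked by Hoxb9 at 5.18. Animal 3 was marked by perinatal myosin Myh8 at 10.92 and the phosphatase gene Ptpru at 7.92. Between the lesions of anomaly animal 2, Ucp1 went from 0.21 to 6.10, Thrsp from 0.21 to 6.00 and Chga from 2.53 to 8.55, while Col10a1 stood at 5.69 in lesion 1 and 0.08 in lesion 2. Adipocyte markers moved with Ucp1 and Thrsp, at a list median of -1.44 in lesion 1 and 2.51 in lesion 2 against normal muscle. These are single libraries without replicates.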
